A study of Mus musculus with 10 samples.

How the data were processed

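RNA from the spleen and lymph nodes of mice was measured on single-colour Affymetrix arrays with biotin-labelled probes. Per the labels, CD4+ T cells had been transduced with GFP or with oncogenic Vav1, put into immunocompromised mice and analysed 6 months later, and total RNA was extracted with Trizol. The table held 10 arrays: 2 GFP spleen, 4 oncogenic Vav1 spleen, 2 GFP lymph node and 2 oncogenic Vav1 lymph node. The descriptions name 7 animals, and 3 of them (CTL2, ONCO2 and ONCO3) gave both tissues. No columns were identical.

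The deposited values are log2 values made by the authors with RMA (background correction, quantile normalization between arrays and summary by median polish) under R 3.6.3, per the submitters' processing notes. The annotation version and any filter were not stated, and no genome build was given, so genes are named by symbol without coordinates. The values ran from 2.42 to 13.9, and the array medians lay between 6.27 and 6.41. These values were used as deposited, and the raw scans were not analysed here.

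Of 29129 probe sets, 19572 had a single gene symbol, 2634 transcript clusters had none and 6923 were controls, among them 5222 intronic and 1324 exonic controls. The 55 genes with more than 1 probe set were represented by that with the highest mean over all arrays, which left 19505 genes. A gene was tested if it lay above the 40th percentile of its own array on at least 2 arrays, which kept 13393 genes and left out 6112. The 40th percentile lay between 5.64 and 5.84 on the log2 scale, and a group mean below that of each of its arrays is called near background in the text. No probe set was annotated to a T cell receptor V segment, so the planned account of segment use was not run.

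Models were fitted with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, with eBayes and a variance trend, and Benjamini-Hochberg adjusted p under 0.05 as the threshold for a change. The spleen and the lymph node comparison of constructs came from a model of the 4 groups, which pools the spread over all 10 arrays because some groups hold 2 arrays (6 residual degrees of freedom). The comparison over both tissues and that of lymph node with spleen came from an additive model of tissue and construct, with the animal as a random block (7 residual degrees of freedom, block correlation -0.35). The difference between the construct effects of both tissues was tested as an interaction, also with the animal as a random block (block correlation -0.11). Changes are log2 differences with their standard error (SE), and limma's moderated test is two-sided. The replicate numbers of the titles were not read as pairs, since GFP and oncogenic Vav1 arrays of the same number carry different animal names.

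The 32 lists of T cell programs, pathways and cell type markers were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. The list tests took no account of the animal block. Lists added after seeing the data were adjusted among themselves alone. Their p-values are no independent support, since the same values led to their choice. The counts of lists take in all 32, and 1 of them is not reported here. Each count of list members over all genes tested is given with the count adjusted over the list alone. None of the 32 passed the threshold in any comparison when camera estimated the correlation between genes from these arrays, and fry, which tests whether the genes of a list move on balance in a single direction, passed 17 lists in spleen, 12 in lymph node and 19 over both tissues. The lists, the models, the filter, the alternatives and the rule for named genes were fixed before the data were examined, unless the text says that something was chosen after seeing the data. The rule for named genes took Vav1 and, per comparison of constructs, the 10 genes with the largest rise and the 10 with the largest fall in log2 among those past the threshold whose groups of arrays did not overlap (5 each way for the interaction and the tissue comparison). Predicted genes without a proper symbol, receptor and immunoglobulin segments and small RNA genes were left out of that ranking. Within a list, up to 4 members with the smallest p could be named, and any member of the T follicular helper list.

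The fits were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. In spleen, 81% of the former and 99% of the latter were recovered, in lymph node 60% and 97%, over both tissues 81% and 100%, for the interaction 41% and 86%, and for tissue 87% and 99%. The simulation gave all groups the same spread of a gene and arrays of an animal a positive correlation. In the data the oncogenic Vav1 lymph node arrays spread more and the block correlations were negative. The recovery therefore holds for the simulated settings alone. Alternatives covered the filter, normalization, variance model, array weights, probe set summary, a fold threshold of 1.5, arrays of a single tissue, blocks, the list test and leaving out each array in turn. Alternatives added after seeing the data were the median intronic control value of each array as a covariate in spleen and the omission of both arrays named ONCO3. For the arrays, their number limits the precision.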

Results

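Transcript levels were measured on 10 arrays from mice that had received CD4+ T cells carrying GFP or an oncogenic form of Vav1, a signalling protein downstream of the T cell receptor. The spleen gave 2 GFP and 4 oncogenic Vav1 arrays, and the lymph node gave 2 of each, all taken 6 months after transfer. The series concerns VAV1 mutations found in cancer and T cell lymphoma, and each comparison of constructs asks which transcripts differed where oncogenic Vav1 T cells had been introduced. The labels call the samples CD4+ T cells, while transcripts of other cell types were abundant on every array. Cd79a, a chain of the B cell receptor, lay at or above percentile 95.3 of the probe sets of each array, the B cell gene Ms4a1 at or above 91.0 and the myeloid lysozyme gene Lyz2 at or above 98.8. The T cell genes Cd3e, Cd8a and Cd4 lay at or above percentiles 82.4, 79.4 and 76.4. Along the axis that held 45.8% of the variance among the genes tested, the 4 GFP arrays lay between -52.5 and -16.9 and the 6 oncogenic Vav1 arrays between 18.3 and 34.0.

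In the spleen, neutrophil, cell cycle, Th1 and cytotoxic transcripts rose with oncogenic Vav1, as did several chemokine genes. Transcripts of B cells and naive T cells fell. Ngp, S100a8, S100a9 and Lcn2, all products of neutrophils, were 18.6-fold, 13.1-fold, 12.6-fold and 17.4-fold higher in the 4 oncogenic Vav1 arrays than in the 2 GFP arrays. All 34 measured genes of the proliferation list rose, with a median log2 change of 1.79. The mitotic kinase Plk1 (2.55, SE 0.23) was among them. The granzyme Gzmk rose by 5.03 (SE 0.47) and the chemokine Ccl5, made by activated T cells, by 2.82 (SE 0.31). The complement receptor Cr2 of B cells changed by -1.94 (SE 0.20) and Lef1, a transcription factor of naive T cells, by -1.61 (SE 0.15). By limma, 3596 of 13393 genes changed, 2288 up and 1308 down. This count was 1089 without GFP spleen replicate 1, 1850 without GFP spleen replicate 2, 2336 and 2338 without oncogenic Vav1 spleen replicates 1 and 2, 5504 and 5520 without oncogenic Vav1 lymph node replicates 1 and 2, which enter through the shared spread, and 2379 with a fold threshold of 1.5 as well. The rises made up 63.6% of the changes, against 79.8% after centring each array on its median, which moved the median of all genes to 0.108, and 56.1% after quantile normalization.

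The spleen genes with the largest rises were the chemokine genes Ccl8 (5.55, SE 0.47, adjusted p = 9.7e-05), Ccl3 (4.99, SE 0.56, adjusted p = 0.00044), Ccl12 (4.36, SE 0.51, adjusted p = 0.00049) and Cxcl9 (3.78, SE 0.49, adjusted p = 8e-04), with Gzmk (adjusted p = 0.00018) and the Fc receptor gene Fcgr4 (4.35, SE 0.26, adjusted p = 1.4e-05). In the GFP spleen, Ccl8, Ccl3, Ccl12, Gzmk and Fcgr4 were near background, so the size of these changes depends on the background level. The neutrophil genes Ngp (4.22, SE 0.18), Lcn2 (4.12, SE 0.21), S100a8 (3.72, SE 0.24) and S100a9 (3.66, SE 0.15) completed the 10. The largest falls were in Car3 (-3.27, SE 0.47), a carbonic anhydrase of muscle and fat, Msh5 (-2.22, SE 0.14), Adipoq (-2.17, SE 0.41), the fat hormone adiponectin, Col6a4 (-2.11, SE 0.17), Cr2, Ly6k (-1.83, SE 0.15), the Y-linked histone demethylase gene Kdm5d (-1.82, SE 0.52), Mid1 (-1.80, SE 0.25), St8sia1 (-1.78, SE 0.20) and Fcer2a (-1.78, SE 0.12), the low-affinity IgE receptor of B cells. Car3, Msh5, Adipoq and Col6a4 were near background in the oncogenic Vav1 spleen. The size and order of these falls depend on the background level. Adjusted p was 0.0013 for Car3, 0.0041 for Adipoq and 0.027 for Kdm5d. Adipoq did not pass without GFP spleen replicate 1 (-1.71, adjusted p = 0.071), and Kdm5d did not pass without GFP spleen replicate 1 (adjusted p = 0.15) or 2 (adjusted p = 0.12). In oncogenic Vav1 spleen replicate 3, Kdm5d was at 4.97 against at least 7.04 in the other arrays of its group. Without both arrays of the animal named ONCO3, this array and oncogenic Vav1 lymph node replicate 2, 5849 genes changed in the spleen, an alternative chosen after seeing the data. Vav1 itself was 0.45 higher (SE 0.21, adjusted p = 0.14), with array values of 9.63 and 9.83 for GFP and 9.99 to 10.3 for oncogenic Vav1, and the labels do not say whether the probes read the introduced form. It passed with the spleen arrays alone (0.45, adjusted p = 0.0096), with array weights (0.44, adjusted p = 0.024) and without oncogenic Vav1 lymph node replicate 1 (adjusted p = 0.0053) or 2 (adjusted p = 0.0049). It was -0.27 (adjusted p = 0.44) with the intronic control covariate described below.

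Among T cell programs in the spleen, 15 of 20 Th1 and cytotoxic genes rose (17 up and 1 down adjusted over the list alone), with a median of 1.07 and camera adjusted p = 4.9e-07 (adjusted p = 0.27 with an estimated correlation). Besides Gzmk, Ccl3 and Ccl5, the T-box factor gene Eomes rose by 2.58 (SE 0.41). Of 13 inhibitory receptor genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 1.16 and camera adjusted p = 0.014 (adjusted p = 0.57 with an estimated correlation). Lag3 rose by 2.79 (SE 0.41), Pdcd1, which encodes PD-1, by 2.61 (SE 0.37), and Ctla4 by 2.05 (SE 0.25), while Btla, which B cells also carry, fell by 1.10 (SE 0.13). Of 13 naive T cell genes, 9 fell (9 adjusted over the list alone), with a median of -0.85 and camera adjusted p = 1.3e-05 (adjusted p = 0.22 with an estimated correlation). The chromatin organizer Satb1 (-1.16, SE 0.16) and the egress receptor S1pr1 (-1.44, SE 0.22) were among them. The T follicular helper list was mixed, with 7 of 20 genes up and 3 down (8 and 4 adjusted over the list alone) and camera adjusted p = 0.45. Its members Tigit (2.43, SE 0.39; near background in GFP), Icos (1.39, SE 0.25) and Sh2d1a (1.5, SE 0.27) rose and Id3 (-1.32, SE 0.21) fell, while the lineage factor Bcl6 (0.21, adjusted p = 0.56) and the homing receptor Cxcr5 (-0.63, adjusted p = 0.08) did not pass. Cxcr5 did pass with quantile normalization (-0.77, adjusted p = 0.042), array weights (adjusted p = 0.0046) or the spleen arrays alone (adjusted p = 0.009), and without oncogenic Vav1 spleen replicate 3 (adjusted p = 0.042) or either oncogenic Vav1 lymph node array (adjusted p = 0.0043 and 0.004). The cytokine gene Il10 of the regulatory T cell list rose by 1.98 (SE 0.33) from near background, and that list had 3 of 11 genes up (4 up and 1 down adjusted over the list alone) with camera adjusted p = 0.19.

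Growth and response pathways rose in the spleen along with the cell cycle. The arrays held transcripts of several cell types, and which cells carried these changes was not tested. Among the spleen arrays, the proliferation and erythroid means were both lowest in GFP replicate 1 (6.91 and 7.01). Both were highest in oncogenic Vav1 replicate 2 (9.29 and 9.94). The proliferation list had camera adjusted p = 5.9e-18 (adjusted p = 0.27 with an estimated correlation; 34 of 34 adjusted over the list alone), with the mitotic kinases Bub1b at 2.75 (SE 0.28), from near background, and Aurkb at 1.95 (SE 0.18). Glycolysis genes rose in 11 of 17 cases (12 adjusted over the list alone), with a median of 1.18 and camera adjusted p = 1.3e-05 (adjusted p = 0.24 with an estimated correlation). Tpi1 (2.05, SE 0.29) and Ldha (1.35, SE 0.14) were among them. Of 24 interferon response genes, 16 rose (16 up and 1 down adjusted over the list alone), with a median of 0.76 and camera adjusted p = 8.8e-06 (adjusted p = 0.27 with an estimated correlation), and the interferon-induced GTPases Iigp1 (3.46, SE 0.46) and Igtp (2.08, SE 0.18) were among them. Ribosome biogenesis and Myc target genes rose in 8 of 20 cases (11 adjusted over the list alone), median 0.38, with camera adjusted p = 0.0027 (adjusted p = 0.22 with an estimated correlation). The spermidine synthase gene Srm (1.27, SE 0.15) was among them. Of 10 Notch pathway genes, 4 fell (5 adjusted over the list alone), median -0.35, with camera adjusted p = 0.0083 (adjusted p = 0.22 with an estimated correlation). Notch2 (-0.89, SE 0.15), a receptor also carried by B cells, was among them. Camera adjusted p was 0.13 for early T cell receptor response genes, 0.20 for NF-kB targets, 0.17 for p53 targets, 0.20 for Th2 genes and 0.11 for Th17 genes.

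Markers of other cell types moved with the construct in the same spleen arrays. Of 13 neutrophil genes, 12 rose (12 adjusted over the list alone), with a median of 2.81 and camera adjusted p = 7.4e-13 (adjusted p = 0.18 with an estimated correlation). Macrophage and monocyte genes rose in 9 of 17 cases and fell in 1 (9 and 1 adjusted over the list alone), median 0.68, with camera adjusted p = 0.00057 (adjusted p = 0.22 with an estimated correlation). The complement genes C1qa (2.50, SE 0.37) and C1qb (2.50, SE 0.35) and the adhesion molecule Vcam1 (1.37, SE 0.16) were among them. B cell genes fell in 8 of 13 cases (10 adjusted over the list alone), median -0.97, with camera adjusted p = 5.2e-07 (adjusted p = 0.22 with an estimated correlation). The B cell factor Ebf1 (-1.52, SE 0.12) was among them. Plasma cell genes rose in 6 of 9 cases (6 adjusted over the list alone), median 0.70, with camera adjusted p = 0.0027 (adjusted p = 0.22 with an estimated correlation). Creld2 (1.61, SE 0.14), an endoplasmic reticulum stress protein, was among them. Germinal centre B cell genes rose in 3 of 7 cases (3 adjusted over the list alone), median 0.67, with camera adjusted p = 0.012 (adjusted p = 0.27 with an estimated correlation). The Myb family gene Mybl1 (2.60, SE 0.19; near background in GFP) was among them. The general T cell list had 2 of 14 genes up and 1 down (the same adjusted over the list alone) and did not pass (median 0.26, camera adjusted p = 0.20). Cd4 rose by 1.04 (SE 0.24) and the adaptor Trat1 changed by -1.05 (SE 0.18). Cd4 did not pass without GFP spleen replicate 1 (1.07, adjusted p = 0.076) or 2 (1.01, adjusted p = 0.071).

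Further marker lists in the spleen depended on single arrays or on the settings, or did not pass. None of 12 erythroid genes passed alone, with Rhag at 2.38 (adjusted p = 0.064) and Car2 at 1.63 (adjusted p = 0.086), while the list median was 1.43 and camera adjusted p was 0.028 (adjusted p = 0.65 with an estimated correlation). Rhag and Car2 passed with the spleen arrays alone (adjusted p = 0.0095 and 0.02), with array weights (0.0094 and 0.02), with the replicate number as a block (0.016 for each) and without oncogenic Vav1 lymph node replicate 1 (0.0045 and 0.011) or 2 (0.0043 and 0.011). They were 1.27 and 0.68 without GFP spleen replicate 1. The erythroid list did not pass without GFP spleen replicate 1 (median 0.69, adjusted p = 0.30) or oncogenic Vav1 spleen replicate 2 (median 1.02, adjusted p = 0.072). In the gamma-delta T cell list only Blk, a kinase that B cells also express, passed (-1.03, SE 0.18), and camera adjusted p was 0.037 (adjusted p = 0.27 with an estimated correlation), with 2 genes down adjusted over the list alone. That list did not pass without GFP spleen replicate 2 (adjusted p = 0.063), oncogenic Vav1 spleen replicate 1 (adjusted p = 0.051) or replicate 3 (adjusted p = 0.055), or with quantile normalization (adjusted p = 0.065). The mast cell and basophil list had 2 of 6 genes up (2 adjusted over the list alone) with camera adjusted p = 0.037 (adjusted p = 0.22 with an estimated correlation), and did not pass without GFP spleen replicate 2 (adjusted p = 0.10) or oncogenic Vav1 spleen replicate 3 (adjusted p = 0.061), or with the replicate number as a block (adjusted p = 0.086). Camera adjusted p was 0.97 for the CD8 genes, 0.20 for dendritic cells, 0.71 for megakaryocytes, 0.63 for stroma and 0.10 for haematopoietic progenitors. For NK cells (adjusted p = 0.81) the median was 0.02 and for endothelium (adjusted p = 0.83) it was 0.06, while camera placed both lists lower with oncogenic Vav1, as it did the CD8 genes with a median of 0.04.

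The arrays of the GFP spleen also differed in their control probe sets. The median intronic control value was 5.87 and 5.69 there, against 5.43 to 5.55 in the oncogenic Vav1 spleen and 5.27 to 5.57 in the lymph node. With this value as a covariate, an alternative chosen after seeing the data, 916 genes changed in the spleen and 725 of them were among the 3596. The covariate was fitted over all 10 arrays, from differences within groups. The largest of these was between oncogenic Vav1 lymph node replicates 1 and 2 (5.27 and 5.57). The correction of the spleen changes thus rests in part on those lymph node arrays. Of the genes named above, 17 then missed the threshold, at adjusted p from 0.05 for C1qb to 0.55 for Cd4. Kdm5d (-2.03, SE 0.88), S1pr1 (-1.30, SE 0.37), Id3 (-1.25, SE 0.36), Sh2d1a (1.21, SE 0.45) and Eomes (2.03, SE 0.66) kept most of their change, with a larger SE. The change itself shrank for Car3 (-2.08, SE 0.65), Adipoq (-0.89, SE 0.48), Mid1 (-1.05, SE 0.30), Pdcd1 (1.25, SE 0.35), Lag3 (1.52, SE 0.49), Tpi1 (0.99, SE 0.27), C1qa (1.04, SE 0.29), C1qb (1.18, SE 0.31), Tigit (1.38, SE 0.52), Icos (0.60, SE 0.29), Il10 (0.80, SE 0.33) and Cd4 (0.25, SE 0.26). Some genes that still passed were also lower, such as Ccl8 (3.67, SE 0.32), Ccl3 (2.95, SE 0.54), Cxcl9 (1.95, SE 0.42) and Iigp1 (1.58, SE 0.31). Under the covariate the proliferation list had 26 genes up and a median of 2.20, the neutrophil list 10 up and a median of 1.94, and the B cell list 12 down and a median of -1.25. The inhibitory receptor list (median 0.38, adjusted p = 0.32), the germinal centre B cell list (median -0.07, adjusted p = 0.44) and the gamma-delta T cell list (median -0.35, adjusted p = 0.12) no longer passed. The glycolysis list (median 0.31, 2 genes up, adjusted p = 0.015) and the interferon list (median 0.44, 3 genes up, adjusted p = 0.015) shrank and still passed. NF-kB targets, with a median of 0.39 before, passed as lower (median -0.38, adjusted p = 0.041), and megakaryocyte genes passed as higher (median 0.66, adjusted p = 0.0059).

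**Figure D1:**
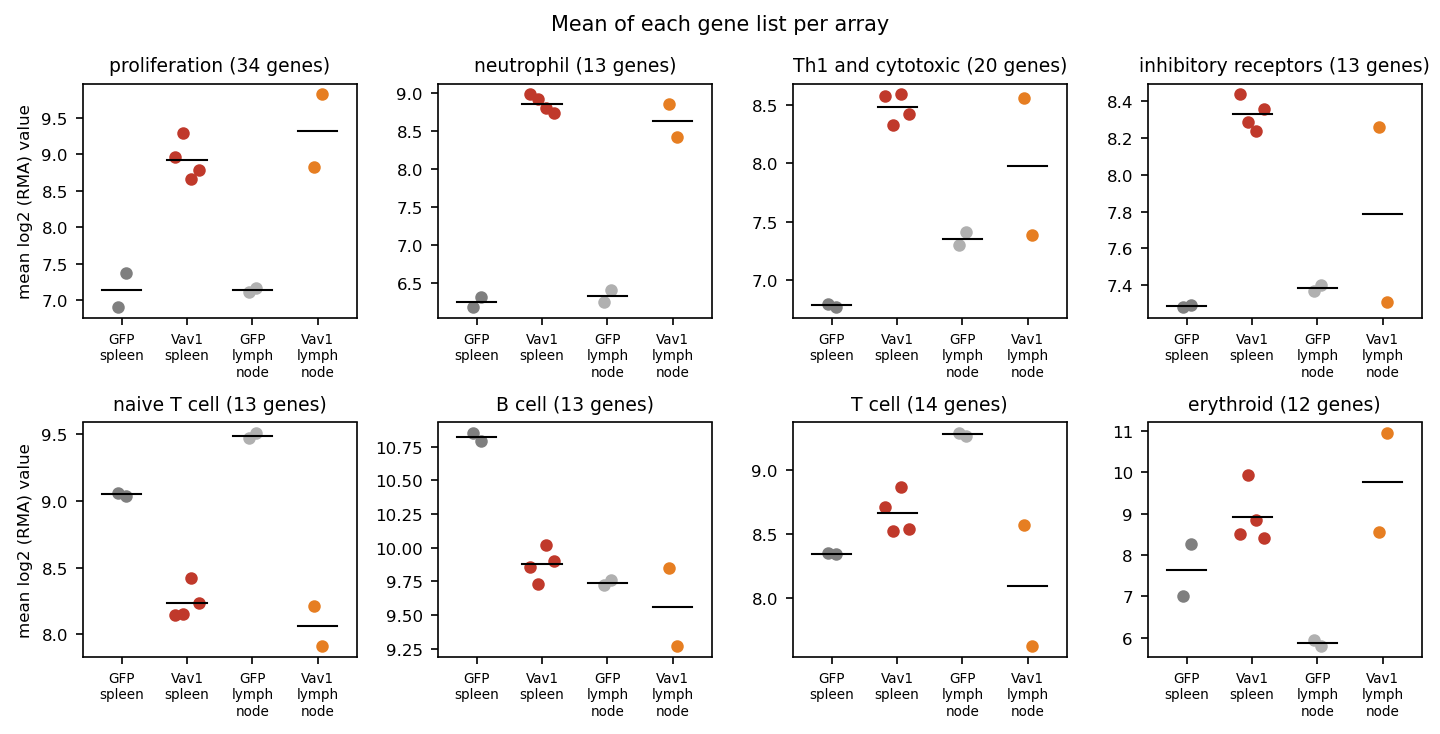
Mean log2 (RMA) value of the genes of 8 lists on each array, with points for arrays, a line for each group mean and groups along the horizontal axis. For the neutrophil list the oncogenic Vav1 spleen mean of 8.86 stood above the GFP mean of 6.24, while for B cells it stood at 9.88 against 10.82, and the 2 oncogenic Vav1 lymph node arrays lay apart for the Th1 and cytotoxic list (8.56 and 7.39).

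In the lymph node, red blood cell, platelet, neutrophil and cell cycle transcripts rose with oncogenic Vav1, and those of T cells, stroma and vessels fell. Rhag, a membrane protein of red cells, was 49.3-fold higher in the 2 oncogenic Vav1 arrays than in the 2 GFP arrays, and the platelet chemokine Ppbp was 34.3-fold higher, both from near background in GFP. Their log2 changes ran from 4.05 to 7.19 and from 4.3 to 5.89 on leaving out each array. All 34 proliferation genes rose, with a median log2 change of 2.17, among them the mitotic kinases Bub1 (3.83, SE 0.31; near background in GFP) and Plk1 (2.59, SE 0.27). Ucp1, the uncoupling protein of brown fat, changed by -6.56 (SE 0.18) and Lum, a matrix protein of fibroblasts, by -2.95 (SE 0.17), both to near background. By limma, 2500 of 13393 genes changed, 1054 up and 1446 down. Without GFP lymph node replicates 1 and 2 in turn the count was 1040 and 1091, without oncogenic Vav1 lymph node replicate 1 it was 4650, with array weights 1264, and with the 4 lymph node arrays alone 433. Rises made up 42.2% of the changes, against 51% without oncogenic Vav1 lymph node replicate 2 and 26.3% with the lymph node arrays alone. Oncogenic Vav1 lymph node replicate 2 stood apart along the axis that held 17.1% of the variance, at 50.6 against -19.1 to 13.5 for the 9 other arrays. It correlated with replicate 1 at 0.957 across probe sets, which are not independent replicates. The mean of the T cell list had an SD of 0.67 in oncogenic Vav1 and 0.01 in GFP lymph node. The shared spread assumes that groups vary alike, so SEs of genes that spread more there may be too small. Both oncogenic Vav1 lymph node arrays also resembled the spleen arrays. A wrong tissue label or mixed spleen RNA, taken up below, cannot be told apart from the construct. The erythroid mean was 10.94 in replicate 2 and 8.56 in replicate 1, against at most 9.94 in the spleen arrays. The T cell mean was 7.62 and 8.57, against at least 8.34 in the spleen arrays. RNA of these spleens alone would not give the values of replicate 2, but another spleen might, and this rests on 1 array.

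The largest rises in the lymph node were in genes of red blood cells, namely Rhag (5.62, SE 0.99, adjusted p = 0.0032), the carbonic anhydrases Car1 (5.10, SE 0.81, adjusted p = 0.0018) and Car2 (5.08, SE 0.74, adjusted p = 0.0011), Epb42 (4.57, SE 0.89), Sptb (4.34, SE 0.82), Hemgn (4.04, SE 0.86) and the blood group gene Kel (4.00, SE 0.85), together with Ppbp (5.10, SE 0.46, adjusted p = 6.1e-05), Pdzk1ip1 (4.47, SE 0.96) and Apol11b (4.12, SE 0.54). Of these, Rhag, Car1, Epb42, Sptb, Kel, Ppbp, Pdzk1ip1 and Apol11b were near background in the GFP lymph node. The size and order of the rises depend on the background level. Leaving out oncogenic Vav1 lymph node replicate 2 lowered Epb42 to 3.03, Hemgn to 2.54 and Kel to 2.45. Without GFP lymph node replicate 1, Pdzk1ip1 (adjusted p = 0.088), Hemgn (0.058) and Kel (0.077) did not pass, and Hemgn did not pass without replicate 2 (adjusted p = 0.065). The largest falls were in Ucp1 (adjusted p = 2.8e-08), Mup9 (-5.68, SE 0.51), Mup19 (-5.61, SE 0.47), Mup22 (-5.22, SE 0.45) and Mup2 (-4.73, SE 0.32), 4 major urinary protein genes so alike that their probes cannot be taken as separate, Retnla (-5.07, SE 0.28), Apod (-4.30, SE 0.19), Cox8b (-3.77, SE 0.18), Folr2 (-3.70, SE 0.17) and Cdo1 (-3.66, SE 0.51). Of these, Cox8b encodes a mitochondrial subunit of brown fat and muscle, and Ucp1, Mup9, Retnla, Apod and Cox8b were near background in the oncogenic Vav1 arrays. The size and order of the falls depend on the background level too. Vav1 itself differed by 0.11 (SE 0.24, adjusted p = 0.80), by -0.34 (adjusted p = 0.11) without oncogenic Vav1 lymph node replicate 1 and by 0.56 (adjusted p = 0.016) without replicate 2.

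**Figure D2:**
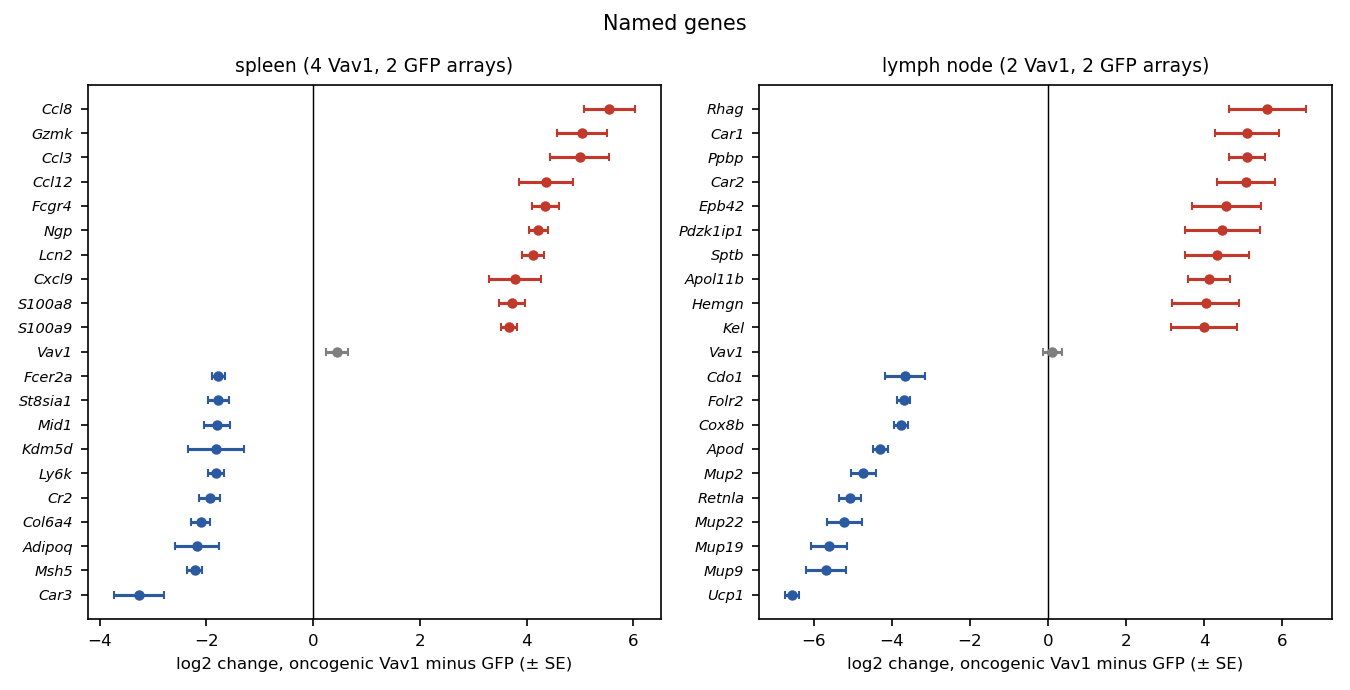
Log2 change, oncogenic Vav1 minus GFP, on the horizontal axis for the named genes of the spleen (left) and the lymph node (right), with points for the estimate and bars for 1 SE; red marks a rise, blue a fall and grey a gene that did not pass. The rises reached 5.55 for Ccl8 in the spleen and 5.62 for Rhag in the lymph node, the falls -3.27 for Car3 and -6.56 for Ucp1, and Vav1 lay at 0.45 and 0.11.

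The blood cell lists rose together in the lymph node. All 12 erythroid genes rose (12 adjusted over the list alone), with a median of 3.94 and camera adjusted p = 2.6e-09 (adjusted p = 0.33 with an estimated correlation). The band 3 gene Slc4a1 (3.77, SE 0.55) and the haem synthesis gene Alas2 (3.73, SE 0.63) were among them. Of 7 megakaryocyte genes, 5 rose (6 adjusted over the list alone), median 1.05, with camera adjusted p = 4.4e-05 (adjusted p = 0.29 with an estimated correlation). Pf4 (1.48, SE 0.28) was among them. Neutrophil genes rose in 11 of 13 cases (12 adjusted over the list alone), median 2.78, with camera adjusted p = 3.4e-13 (adjusted p = 0.10 with an estimated correlation), with Ngp at 3.85 (SE 0.21), S100a8 at 3.66 (SE 0.28), S100a9 at 3.32 (SE 0.17) and Lcn2 at 3.01 (SE 0.25). Plasma cell genes rose in 6 of 9 cases (6 adjusted over the list alone), median 0.73, with camera adjusted p = 4.4e-05 (adjusted p = 0.12 with an estimated correlation). The immunoglobulin joining chain gene Jchain (2.29, SE 0.30) was among them. The proliferation list had camera adjusted p = 4e-26 (adjusted p = 0.25 with an estimated correlation; 34 of 34 adjusted over the list alone). Its mean was highest of all arrays in oncogenic Vav1 lymph node replicate 2 (9.82). There the erythroid mean was also highest (10.94) and the T cell mean lowest (7.62), and which cells carried the cell cycle transcripts was not tested. Ribosome biogenesis and Myc target genes rose in 8 of 20 cases (11 adjusted over the list alone), median 0.40, with camera adjusted p = 9.1e-07 (adjusted p = 0.10 with an estimated correlation). The polyamine enzyme gene Odc1 (2.19, SE 0.41) was among them.

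T cell, stromal and endothelial lists fell in the lymph node. T cell genes fell in 9 of 14 cases (13 adjusted over the list alone), median -1.15, with camera adjusted p = 7.1e-07 (adjusted p = 0.33 with an estimated correlation). Trat1 (-2.31, SE 0.21; near background in oncogenic Vav1) and the lineage factor Bcl11b (-1.53, SE 0.26) were among them. The list mean was 9.29 and 9.27 in GFP and 8.57 and 7.62 in oncogenic Vav1 replicates 1 and 2, and without replicate 2 the median was -0.65 (adjusted p = 4.5e-05). Naive T cell genes fell in 12 of 13 cases (12 adjusted over the list alone), median -1.27, with camera adjusted p = 8.4e-10 (adjusted p = 0.10 with an estimated correlation). Dapl1 (-3.01, SE 0.32) and Lef1 (-2.73, SE 0.18) were among them. Both CD8 genes fell (2 adjusted over the list alone), median -1.72, with camera adjusted p = 0.027 (adjusted p = 0.33 with an estimated correlation), Cd8b1 by 1.83 (SE 0.28). Stromal genes fell in 8 of 13 cases (10 adjusted over the list alone), median -1.04, with camera adjusted p = 7.1e-07 (adjusted p = 0.12 with an estimated correlation). The collagen gene Col3a1 (-2.87, SE 0.18) and the T zone chemokine Ccl21a (-2.43, SE 0.37) were among them, and the list median was -0.53 (adjusted p = 3.3e-05) without oncogenic Vav1 replicate 2. Endothelial genes fell in 6 of 13 cases and rose in 1 (8 and 1 adjusted over the list alone), median -0.57, with camera adjusted p = 0.0012 (adjusted p = 0.10 with an estimated correlation). The lymphatic receptor Lyve1 (-2.62, SE 0.26) and the junction protein Cdh5 (-1.42, SE 0.17) were among them. Beside these lists, all 15 genes of a fat cell list chosen after seeing the data fell (15 adjusted over the list alone), median -2.63, with camera adjusted p = 9.7e-16 (adjusted p = 0.086 with an estimated correlation). The stromal and endothelial falls were not separated from this loss of fat transcripts.

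The calls of 3 further lists in the lymph node turned on single arrays. Th1 and cytotoxic genes had 5 of 20 up and 2 down (7 and 2 adjusted over the list alone), median 0.32, with camera adjusted p = 0.039 (adjusted p = 0.69 with an estimated correlation), and the median was -0.09 without oncogenic Vav1 replicate 1 (adjusted p = 0.82) and 0.88 without replicate 2 (adjusted p = 1.6e-06). Adjusted p was 0.07 without oncogenic Vav1 spleen replicate 3 and 0.066 with the replicate number as a block. Gzmk rose by 3.73 (SE 0.54) from near background. Interferon response genes had 7 of 24 up (8 up and 1 down adjusted over the list alone), median 0.61, with camera adjusted p = 0.0055 (adjusted p = 0.59 with an estimated correlation), and the median was 0.15 without oncogenic Vav1 replicate 1 (adjusted p = 0.15) and 0.97 without replicate 2 (adjusted p = 1.3e-05). Dendritic cell genes had 5 of 12 down and 1 up (5 and 1 adjusted over the list alone), median -0.37, with camera adjusted p = 0.035 (adjusted p = 0.48 with an estimated correlation). Ccr9 (-2.03, SE 0.26) and Cd209a (-1.77, SE 0.24; near background in oncogenic Vav1) were among them. The list did not pass without oncogenic Vav1 replicate 1 (adjusted p = 0.056) or 2 (adjusted p = 0.11).

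Other lists did not pass in the lymph node. The T follicular helper list had 4 of 20 genes down (4 adjusted over the list alone) with camera adjusted p = 0.62. Cd40lg (-2.06, SE 0.18; near background in oncogenic Vav1) and Id3 (-1.52, SE 0.24) were among them. Early T cell receptor response genes had 2 of 22 up and 5 down (2 and 8 adjusted over the list alone) with camera adjusted p = 0.054, and the immediate early genes Fos (-1.67, SE 0.18) and Egr1 (-1.51, SE 0.23) fell. Camera adjusted p was 0.23 for inhibitory receptors, 0.24 for glycolysis, 0.18 for regulatory T cells, 0.25 for Th2, 0.78 for Th17, 0.40 for NF-kB targets, 0.83 for Notch targets and 0.78 for p53 targets. It was 0.48 for gamma-delta T cells, 0.41 for B cells, 0.21 for germinal centre B cells, 0.33 for macrophages, 0.21 for NK cells, 0.78 for mast cells and basophils and 0.22 for progenitors. With the 4 lymph node arrays alone, Rhag, Car1, Epb42, Pdzk1ip1, Sptb, Hemgn, Kel, Cdo1, Alas2, Pf4, Jchain, Bcl11b, Gzmk, Odc1 and Egr1 missed the threshold, at adjusted p from 0.065 for Car1 and Jchain to 0.13 for Kel.

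Over both tissues together, neutrophil, cell cycle and cytotoxic transcripts rose and naive T cell transcripts fell. The comparison averages the construct effect over the tissues, with the tissue taken into account, and does not test whether a change held in each of them. Gzmk was 20.6-fold higher (log2 4.36, SE 0.34, adjusted p = 1.5e-05) and Ngp 16.8-fold higher (log2 4.07, SE 0.13, adjusted p = 4.1e-08) in the 6 oncogenic Vav1 arrays than in the 4 GFP arrays. Lef1 fell by 2.09 (SE 0.16) and the naive T cell gene Dapl1 by 2.26 (SE 0.22). Without the animal block 2963 genes changed. The block correlation of -0.35 means that residuals of arrays of the same animal name went apart in the additive model, which narrows the SE of the construct. That model leaves out any difference of the construct effect between the tissues. With this difference in the model the block correlation was -0.11. The -0.35 therefore cannot be read as a property of the animals alone, and the count with the block may be too high. By limma with the block, 4247 genes changed, 2327 up and 1920 down, and 1983 did so with a fold threshold of 1.5 as well. The count was 2112 without GFP spleen replicate 1 and 2379 without GFP lymph node replicate 2, and the share of rises was 54.8%, against 65.2% after centring each array and 49.5% after quantile normalization.

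The other large rises over both tissues were in Rhag (4.01, SE 0.68), Ccl3 (3.86, SE 0.49), Fcgr4 (3.83, SE 0.21), S100a8 (3.67, SE 0.17), Lcn2 (3.57, SE 0.20), S100a9 (3.54, SE 0.12), Apol11b (3.50, SE 0.35) and the protease gene Adamdec1 (3.43, SE 0.12), with adjusted p from 4.1e-08 for S100a9 to 0.0015 for Rhag. The large falls were in Car3 (-3.11, SE 0.31), Adipoq (-2.61, SE 0.29), the lectin gene Cd209d (-2.17, SE 0.24), Cdo1 (-2.11, SE 0.48), Psca (-1.99, SE 0.24) and the near-identical chemokine genes Ccl21a, Ccl21b and Ccl21c (each -2.02, SE 0.24). Cdo1 did not pass without GFP lymph node replicate 2 (-1.81, adjusted p = 0.054). Ccl3 and Fcgr4 were near background in the GFP spleen, Rhag and Apol11b in the GFP lymph node, Gzmk and Adamdec1 in both GFP groups, and Car3 and Adipoq in the oncogenic Vav1 spleen. Psca was so in both oncogenic Vav1 groups and Cd209d in all groups but the GFP lymph node. The size of these changes depends on the background level. Vav1 was 0.28 higher (SE 0.14, adjusted p = 0.15). It passed with array weights (0.37, adjusted p = 0.023) and without oncogenic Vav1 spleen replicate 3 (0.35, adjusted p = 0.037) or oncogenic Vav1 lymph node replicate 2 (0.45, adjusted p = 0.00049). Taken tissue by tissue, 623 genes rose in both, where 180.1 would be shared if the calls were independent, 298 fell in both, where 141.2 would be, and 179 changed in opposite directions. Both comparisons share animals and an estimate of the spread, so the calls are not independent. The counts under independence give a scale alone. The spleen and lymph node changes correlated across genes at r = 0.46, and genes are not independent replicates.

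Of 32 lists, 14 passed over both tissues, 12 up and 2 down. Passing here does not mean a change in each tissue. In the lymph node alone camera adjusted p was 0.41 for B cells, 0.24 for glycolysis and 0.33 for macrophages. It was 0.23 there for inhibitory receptors and 0.21 for germinal centre B cells, and 0.71 in the spleen alone for megakaryocytes. All 34 proliferation genes rose (34 adjusted over the list alone; median 2.07, camera adjusted p = 9.8e-29, adjusted p = 0.24 with an estimated correlation). Plk1 (2.57, SE 0.14) and Aurkb (1.98, SE 0.11) were among them. Of 13 neutrophil genes, 12 rose (12 adjusted over the list alone; median 2.74, camera adjusted p = 3.2e-16, adjusted p = 0.099 with an estimated correlation). Th1 and cytotoxic genes had 16 of 20 up and 2 down (the same adjusted over the list alone; median 0.92, camera adjusted p = 7.7e-06, adjusted p = 0.38 with an estimated correlation). All 12 erythroid genes rose (12 adjusted over the list alone; median 2.84, camera adjusted p = 7.7e-06, adjusted p = 0.38 with an estimated correlation). Naive T cell genes had 12 of 13 down (12 adjusted over the list alone; median -0.95, camera adjusted p = 1.6e-08, adjusted p = 0.21 with an estimated correlation). Satb1 (-1.39, SE 0.12) was among them. B cell genes had 8 of 13 down (9 adjusted over the list alone; median -0.54, camera adjusted p = 0.00027, adjusted p = 0.40 with an estimated correlation). Fcer2a (-1.63, SE 0.09) and Ebf1 (-1.18, SE 0.12) were among them. Interferon response genes had 17 of 24 up (18 up and 1 down adjusted over the list alone; median 0.85, camera adjusted p = 7.7e-06, adjusted p = 0.33 with an estimated correlation).

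Plasma cell genes had 8 of 9 up over both tissues (8 adjusted over the list alone; median 0.74, camera adjusted p = 3.9e-05, adjusted p = 0.14 with an estimated correlation). Creld2 (1.44, SE 0.11) was among them. Ribosome biogenesis and Myc target genes had 13 of 20 up (14 adjusted over the list alone; median 0.43, camera adjusted p = 2.3e-06, adjusted p = 0.14 with an estimated correlation). Glycolysis genes had 7 of 17 up (10 adjusted over the list alone; median 0.68, camera adjusted p = 2e-04, adjusted p = 0.33 with an estimated correlation). Macrophage genes had 9 of 17 up and 1 down (the same adjusted over the list alone; median 0.53, camera adjusted p = 0.0064, adjusted p = 0.38 with an estimated correlation). Inhibitory receptor genes had 7 of 13 up and 2 down (the same adjusted over the list alone; median 0.78, camera adjusted p = 0.023, adjusted p = 0.43 with an estimated correlation). Pdcd1 (2.02, SE 0.30) and Tigit (1.75, SE 0.32; near background in GFP spleen) were among them. The list did not pass without oncogenic Vav1 lymph node replicate 1 (adjusted p = 0.054). Germinal centre B cell genes had 3 of 7 up (4 adjusted over the list alone; median 0.31, camera adjusted p = 0.019, adjusted p = 0.38 with an estimated correlation), and also did not pass without that array (adjusted p = 0.054), while the median was 0.58 without replicate 2 (adjusted p = 0.0037). Megakaryocyte genes had 4 of 7 up (4 adjusted over the list alone; median 0.60, camera adjusted p = 0.026, adjusted p = 0.46 with an estimated correlation), and did not pass without GFP lymph node replicate 1 (adjusted p = 0.066) or 2 (0.062), or oncogenic Vav1 lymph node replicate 1 (0.05) or 2 (0.11). The 18 other lists did not pass over both tissues. For early T cell receptor response genes the median was -0.15 and the mean 0.05 (camera adjusted p = 0.94), and for mast cells and basophils the median was -0.02 and the mean 0.18 (camera adjusted p = 0.29).

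The construct effect differed between the tissues for single genes such as Ppbp of platelets, Ucp1 of brown fat and the chemokine gene Ccl8, as the interaction tested. Ppbp had an effect 4.94 higher in the lymph node than in the spleen (SE 0.63, adjusted p = 0.0011), with group means of 9.36 and 9.57 in GFP and oncogenic Vav1 spleen and 4.86 and 9.95 in lymph node. Coch, which encodes the extracellular protein cochlin, differed by 4.82 (SE 0.54, adjusted p = 0.00058), with means of 10.31 and 9.23 in spleen and 5.60 and 9.29 in lymph node. Ccl8 differed by -6.91 (SE 0.75, adjusted p = 0.00051), with means of 4.64 and 10.20 in spleen and 10.39 and 9.04 in lymph node. For Ppbp, Coch and Ucp1 (3.82 against 3.84), the oncogenic Vav1 lymph node mean lay near that of the oncogenic Vav1 spleen. A wrong tissue label or spleen RNA in the lymph node arrays, taken up below, cannot be told apart from a construct effect here. By limma, 1077 genes differed, 125 with a higher and 952 with a lower effect in the lymph node. The higher effects made up 11.6%, against 5.6% after centring each array, 17.6% after quantile normalization, and 32.6% and 29% without oncogenic Vav1 lymph node replicates 1 and 2. The count was 612 and 634 without GFP spleen replicates 1 and 2, 704 without oncogenic Vav1 spleen replicate 1, 384 and 497 without GFP lymph node replicates 1 and 2, and 4201 and 2204 without oncogenic Vav1 lymph node replicates 1 and 2.

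Other higher effects in the lymph node were those of Alas2 (3.65, SE 0.83, adjusted p = 0.024), Gdpd2 (3.02, SE 0.31, adjusted p = 0.00044) and Slc4a1 (2.83, SE 0.73, adjusted p = 0.041). Alas2 and Slc4a1 did not pass without GFP spleen replicate 2 (adjusted p = 0.11 and 0.16), oncogenic Vav1 spleen replicate 1 (0.054 and 0.088) or 4 (0.055 and 0.08), or GFP lymph node replicate 1 (0.093 and 0.15) or 2 (0.088 and 0.12), and Alas2 was 2.41 without oncogenic Vav1 lymph node replicate 2. Other lower effects were those of Ucp1 (-6.44, SE 0.24, adjusted p = 9.2e-07), Mup9 (-5.58, SE 0.71), Mup19 (-5.44, SE 0.66) and Ccl12 (-5.25, SE 0.82, adjusted p = 0.0036). Ppbp, Coch and Gdpd2 were near background in the GFP lymph node, Ccl8 and Ccl12 in the GFP spleen, Mup19 in both spleen groups, and Mup9 and Ucp1 in all groups but the GFP lymph node. The size of these differences depends on the background level. The general T cell list differed by a median of -1.46, with 9 of 14 genes lower (14 adjusted over the list alone) and camera adjusted p = 4.5e-07 (adjusted p = 0.41 with an estimated correlation). In the proliferation list no gene differed between the tissues (0 adjusted over the list alone), and the median difference was 0.43 with camera adjusted p = 0.0073 (adjusted p = 0.61 with an estimated correlation).

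Between the tissues themselves, genes expressed in fat were higher in the lymph node arrays than in the spleen arrays. The additive model asks which transcripts differed by tissue whatever the construct. Car3 (5.47, SE 0.38, adjusted p = 0.00011), Adipoq (5.14, SE 0.37, adjusted p = 0.00011), the fatty acid binding protein gene Fabp4 (4.75, SE 0.31, adjusted p = 0.00011), the hormone gene Retn (4.17, SE 0.43, adjusted p = 0.0037) and Cdo1 (3.6, SE 0.59, adjusted p = 0.049) led 22 genes, all higher in the lymph node. Car3, Adipoq and Retn were near background in the oncogenic Vav1 spleen. Cdo1 passed only without oncogenic Vav1 lymph node replicate 1 among the fits that left out an array, and adjusted p in the others reached 0.21 without GFP lymph node replicate 1. No gene was lower by limma, although 2104 genes in either direction had an unadjusted p under 0.05, and the next by p were Lat2 (-0.87, adjusted p = 0.054), Arhgap15 (-0.57, adjusted p = 0.058), S100pbp (-0.66, adjusted p = 0.069), Mbtd1 (-0.60, adjusted p = 0.078) and Bhlhe41 (-1.04, adjusted p = 0.097). All 5 passed with array weights and without oncogenic Vav1 lymph node replicate 1, where adjusted p for Lat2 was 0.00093 and 0.002. Lat2, Arhgap15 and S100pbp also passed without the animal block, Lat2 without the filter and Arhgap15 without oncogenic Vav1 lymph node replicate 2. Of the fat cell list chosen after seeing the data, 7 of 15 genes were higher in the lymph node (15 adjusted over the list alone), median 2.72, with camera adjusted p = 2e-23 (adjusted p = 0.11 with an estimated correlation). The count of 22 genes was 1030 without oncogenic Vav1 lymph node replicate 1, of which 472 were lower, and leaving out any other array gave 4 to 12. The 12, without oncogenic Vav1 lymph node replicate 2, were 6 higher and 6 lower, and with array weights 963 of 2750 were lower. Oncogenic Vav1 lymph node replicate 1 correlated with the oncogenic Vav1 spleen arrays at 0.981 to 0.987 across probe sets and with the GFP lymph node arrays at 0.957 and 0.959, and probe sets are not independent replicates.

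**Figure D3:**
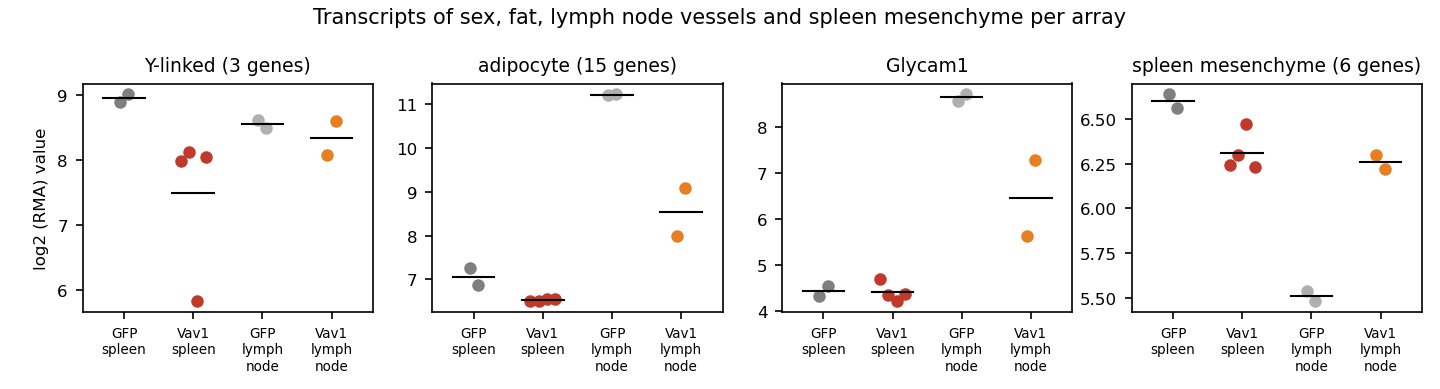
Log2 (RMA) value on each array of 3 Y-linked genes (mean), 15 fat cell genes (mean), the lymph node vessel gene Glycam1 and 6 spleen mesenchyme genes (mean), with points for arrays and a line for each group mean. The fat cell mean was 11.21 in the GFP lymph node group and 8.53 in the oncogenic Vav1 lymph node group, against 7.06 and 6.53 in the spleen, and 1 oncogenic Vav1 spleen array had a Y-linked mean of 5.82.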

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

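The tests of the 3 patterns below were all chosen after the result was seen, while the counts of other splits of the samples had been planned.

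The oncogenic Vav1 lymph node arrays resembled the spleen arrays. For replicate 2 the mean of the fat cell list, a list chosen after seeing the data, lay 1.81 above the highest of the 6 spleen arrays, whose whole range was 0.77, which argues against a wrong tissue label for that array. For replicate 1 the same difference was 0.71, within that range, and although its mean of 7.98 lay above the oncogenic Vav1 spleens, which reached 6.55, and Glycam1 was 5.61, below the 40th percentile of that array, against at most 4.68 in any spleen array, a wrong label cannot be told apart from a lymph node with little fat, as the GFP spleens held some fat as well. Spleen RNA mixed into the lymph node RNA may have contributed, since 6 genes of spleen mesenchyme were 0.75 higher there than in GFP lymph node, at percentile 99.6 of 10000 lists matched for expression, although their GFP lymph node mean of 5.51 was near background, on which the size of the shift depends. Their mean was 6.30 and 6.22 in replicates 1 and 2, against 6.23 to 6.47 in the oncogenic Vav1 spleens. For replicate 2 this goes the other way from the fat cell list and from Glycam1. Glycam1 was 7.28 there, against at most 4.68 in any spleen array and 8.56 and 8.71 in GFP lymph node. Mixed spleen RNA could give the mesenchyme mean as well as a wrong label could, so the mesenchyme genes do not settle the label of replicate 2. Entry of blood cells shared with the spleen stays open, as the neutrophil list rose in the lymph node by 88.1% of its rise in the spleen, and so does the construct itself.

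Y-linked transcripts were low in the spleen array of the animal named ONCO3. The mean of 3 Y-linked genes was 5.82 there against 7.99 for the nearest array of its group, and Kdm5d alone was 4.97 against 7.04. The lymph node array of the same name was 2.79 higher, against differences of -0.38 for CTL2 and -0.04 for ONCO2, which is what samples of different animals could give. A smaller share of male donor T cells cannot be told apart from this. The T cell list, -1.24 in the lymph node array relative to the spleen array, was used as a test. It cannot decide, because it does not part donor from host T cells, and the labels give no sex of either.

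Cytotoxic and Th1 genes were higher in the oncogenic Vav1 spleen. A larger share of T cells is argued against as the whole cause, since the list mean rose by 1.38 more than that of the T cell list between GFP and oncogenic Vav1 arrays. The difference in intronic control signal stays open. With it as a covariate the list median was 0.78, where it had been 1.07, and camera adjusted p was 0.00031, although 3 of its genes then passed where 15 had. This cannot decide for the spleen, because the fit of the covariate rests in part on the oncogenic Vav1 lymph node arrays. A shift of the T cells toward cytotoxic programs under oncogenic Vav1 and the entry of other cells that carry these transcripts both stay open as hypotheses.

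In the same array, oncogenic Vav1 spleen replicate 3, the CD8 list was 9.97 against 9.16 for the nearest array, the NK cell list 7.21 against 6.62 and the Notch target list 7.25 against 7.20. With the 2 Y-linked values above, 5 values stood far from the other arrays relative to the range of the group, among 55 values tested, and chance marks about 1 in 20 such groups. Kdm5d is 1 of the 3 Y-linked genes, so the 5 are not separate, and the Notch target gap was small beside the GFP spleen values of 7.68 and 7.55.

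The construct effect differed between lymph node and spleen, by a test of the difference, for 10 named genes. It was higher in lymph node by 4.94 for Ppbp, 4.82 for Coch, 3.65 for Alas2, 3.02 for Gdpd2 and 2.83 for Slc4a1. It was lower in lymph node for Ccl8 (-6.91), Ucp1 (-6.44), Mup9 (-5.58), Mup19 (-5.44) and Ccl12 (-5.25). Of the lists, 16 differed by camera at the preset correlation and 0 with an estimated correlation. Of the 15 described here, median differences were positive for erythroid (2.82), megakaryocyte (1.17), B cell (0.57), Notch target (0.46) and proliferation genes (0.43). They were negative for CD8 (-1.74), T cell (-1.46), glycolysis (-1.21), stromal (-1.09), Th1 and cytotoxic (-1), regulatory T cell (-0.86), macrophage (-0.79), early T cell receptor response (-0.66), endothelial (-0.61) and naive T cell genes (-0.59).

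Among 1456 transcript clusters without a gene name that passed the filter, which no comparison used, 371 changed in spleen and 192 in lymph node.

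For the construct over both tissues, 1 of the 35 splits of the 7 animals, the real one, gave as many genes, 4164 with the block correlation taken from every seventh gene against at most 1855 in the others. A first rank among 35 splits is the most that they can show. It argues against chance as the source of that count and cannot exclude it. The splits take both arrays named ONCO3 as from 1 animal, as the animal block does. For lymph node against spleen, 6 of the 99 drawn splits of the 10 arrays that could be fitted, the real one among them, gave as many as the real 22 genes, the highest 6871, so chance cannot be excluded there. Splits with several times the real count point to a structure of the samples, which was not tested further. That with 6871 set oncogenic Vav1 spleen replicates 1, 2 and 4 and oncogenic Vav1 lymph node replicate 1 apart from the rest, and another with 6548 mixed tissues and constructs, with GFP spleen replicate 2, oncogenic Vav1 spleen replicate 3, GFP lymph node replicate 2 and oncogenic Vav1 lymph node replicate 2 set apart.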

How the results depend on the processing

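The alternatives without both ONCO3 arrays and with the intronic control covariate were chosen after seeing the data. For the counts of changed genes, all alternatives that are not named here gave a value within 1.5 times that reported. In spleen the count was 2379 with a fold threshold of 1.5, which is stricter by construction, 5849 without both ONCO3 arrays and 916 with the intronic covariate. With the spleen arrays alone the spleen count was 5051, so fewer degrees of freedom need not lower it. In lymph node the count was 1264 with array weights and 433 with the 4 lymph node arrays alone, where 2 residual degrees of freedom remain. Over both tissues it was 1983 with the fold threshold and 6754 without both ONCO3 arrays, which gave 2726 for the interaction. For lymph node against spleen it was 5 with the stricter filter, 5 with centred arrays, 7 with robust eBayes and 2750 with array weights. The cause was not tested for these, the fold threshold apart. Leaving out each array gave 1089 to 5520 genes in spleen, 1040 to 4650 in lymph node, 2112 to 6108 over both tissues, 384 to 4201 for the interaction and 4 to 1030 for tissue, and a group left with 1 array is assumed to vary like the others.

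Lists past the threshold were 0 with an estimated correlation in spleen, lymph node and both tissues, and 14 to 18, 14 to 18 and 12 to 18 on leaving out each array. Vav1 in spleen turned to -0.27 and Bcl6 to -0.49 with the intronic covariate, and Vav1 in lymph node ran from -0.34 to 0.56 on leaving out arrays, where the 0.56 passed (adjusted p = 0.016). The cause of these moves was not tested. Of the genes named that passed, 35 of 52 in spleen, 33 of 48 in lymph node, 27 of 28 over both tissues, 8 of 10 for the interaction and 4 of 5 for tissue passed under every alternative run. Taking the replicate number as a block gave 2674 genes in spleen and 2128 in lymph node, with 15 and 14 lists, although residuals of arrays of the same number correlated at 0.04 and 0.30 in spleen and -0.06 in lymph node across genes. Residuals of arrays of the same animal name correlated at 0.03 for CTL2, -0.51 for ONCO2 and 0.02 for ONCO3. Each such pair takes in an array of a lymph node group of 2 arrays, whose residuals are opposite. The values can therefore neither bear out nor refute the animal names used for the block. The spleen array of ONCO2 correlated at 0.51 with the lymph node array of ONCO3. That value mirrors the -0.51, since residuals of 2 arrays in a group are opposite. Without the animal block 2963 genes changed over both tissues, 1235 for the interaction and 30 for tissue. T cell receptor V segments were not run for want of annotated probe sets. Genes near background, below 5.64 to 5.84 on the log2 scale, set the limit of detection.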

Other observations

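The gene lists of this part were chosen after the values were seen. In the spleen, mitochondrial respiratory chain genes rose with oncogenic Vav1 in 15 of 19 cases (19 adjusted over the list alone), with a median log2 change of 0.61 and camera adjusted p = 2.6e-08 (adjusted p = 0.12 with an estimated correlation). In the lymph node, 9 of the same 19 genes fell (10 adjusted over the list alone), with a median of -0.44 and camera adjusted p = 1.6e-05 (adjusted p = 0.15 with an estimated correlation). In the same arrays the mean of the fat cell list went from 11.21 to 8.53 and that of a brown fat list from 8.29 to 5.14, so the fall was not separated from the loss of fat transcripts. By the interaction the effect was lower in lymph node for 16 of 19 genes (18 adjusted over the list alone), with a median of -1.07 and camera adjusted p = 1.6e-13 (adjusted p = 0.029 with an estimated correlation). Group means of the list were 9.09 and 9.75 in GFP and oncogenic Vav1 spleen and 10.22 and 9.75 in lymph node.

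Antigen presentation genes rose in the spleen in 8 of 17 cases (8 adjusted over the list alone), median 0.72, with camera adjusted p = 0.0029 (adjusted p = 0.45 with an estimated correlation). In the lymph node 1 of the 17 rose (0 adjusted over the list alone), median 0.02, with camera adjusted p = 0.70, and the interaction median was -0.52 (camera adjusted p = 0.0088, adjusted p = 0.56 with an estimated correlation). Cholesterol synthesis genes rose in the spleen in 6 of 11 cases (7 adjusted over the list alone), median 0.57, with camera adjusted p = 0.0081 (adjusted p = 0.35 with an estimated correlation). In the lymph node 1 of the 11 rose and 2 fell (the same adjusted over the list alone), median -0.12, with camera adjusted p = 0.70, and the interaction median was -0.52 (camera adjusted p = 0.0085, adjusted p = 0.37 with an estimated correlation). Endoplasmic reticulum stress genes rose in 5 of 8 cases in spleen (6 adjusted over the list alone), median 0.45, and in 4 of 8 in lymph node with 1 down (the same adjusted over the list alone), median 0.50. Their camera adjusted p was 0.0081 in spleen (adjusted p = 0.21 with an estimated correlation) and 0.042 in lymph node (adjusted p = 0.25 with an estimated correlation). Brown fat genes fell in the lymph node in 7 of 7 cases (7 adjusted over the list alone), median -2.97, with camera adjusted p = 8.4e-13 (adjusted p = 0.0022 with an estimated correlation). Spleen mesenchyme genes rose in the lymph node in 4 of 6 cases (4 adjusted over the list alone), median 0.79, with camera adjusted p = 0.001 (adjusted p = 0.048 with an estimated correlation).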
